A study of Nymphaea colorata with 5 samples.

How the data were processed

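The deposited files hold, for each of 5 sections, a list of 24059 gene IDs and 2 sets of spot names, spot positions and sparse matrices, at spot levels 4 and 7. Per the labels, fresh tissue was frozen and embedded, 10 µm sections were cut, and libraries were made on BMK S1000 slides. The deposited matrices hold raw counts per gene and spot: every entry was whole, no section had been scaled, and the level 4 totals lay −0.687% to 0.446% from those of level 7, so the levels hold nearly but not exactly the same number of counts. These counts are taken here as counts of unique molecular identifiers (UMIs). The aligner, the genome build, the counting tool and the way in which spots over tissue were chosen are not given in the sources used here. Spot positions are in units that the files do not state. Neighbouring spots lie 4.27 units apart at level 4 and 7.9 at level 7 on a hexagonal lattice.

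A spot can hold several cells or part of 1 cell, so spots are regions of tissue and not replicates. The list of genes of stage 4 section 1 has 38 IDs in another order than in the other sections, and each matrix was read with the list of its own section. For these 38 genes the log2 level then correlated with stage 4 section 2 at r = 0.82, against −0.43 with the order of the other sections. All spots in the files were used for sums over sections. The reference table at hand has 24583 genes and matched 0 of the 24059 IDs, so no ID could be paired with a name or description.

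Before the data were examined, 27 gene lists (floral organ identity, pollen, pigment, photosynthesis and others), defined by patterns in gene descriptions, had been fixed together with tests of these lists. With no descriptions for the IDs, none of the lists could be filled, and the list tests across stages, between outer and inner spots, between regions and for spatial autocorrelation were not run. What was kept from that plan is the part that needs no names. The rule for the named genes was fixed then as well: with IDs that cannot be paired with names, the 2 genes furthest up and the 2 furthest down per comparison. Between outer and inner spots this was taken over called genes on the same side in 4 of 4 stages. The genes given with Moran's I are those with the highest index of a section and were chosen after their values were seen.

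Stages were compared by CPM, computed here as the summed UMIs of a gene in a section scaled to a common total of all its UMIs. A gene counted as changed at 2-fold or more on the log2(CPM + 1) scale, with at least 50 CPM in the higher stage, and for stage 4 only if both sections lay on the same side. Unless a bootstrap is named, intervals of levels and ratios are 95% exact intervals of the counts and cover counting error only. For a gene with 0 UMIs, 3 counts set the limit, which is 0.759 CPM in stage 1, 0.522 in stage 2, 0.128 in stage 3, and 2.27 and 0.982 in the stage 4 sections, and a fold against it is a lower bound. The interval of the share of genes 2-fold apart treats genes as independent, which they are not.

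For outer and inner spots, the distance of each level 7 spot to the outline of the tissue was measured on the lattice with inner gaps filled, and the 33.3% of the spots at the smallest and at the largest distance were summed. The stage 4 sections were added together, which leaves 8 sums. The sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, stage as a block, Benjamini-Hochberg adjustment at 0.05), with DESeq2 1.42.0 as an alternative. The stages act as replicates of this contrast, so the p-values measure the spread between these stages. A difference carried by some of the stages can be called, so a call does not mean the same side in every stage. After the fit of the real data, the test was also run on counts simulated from the stage levels and dispersions of that fit. In these counts 200 genes were changed by known folds over 14909 genes, and 7 unchanged genes were called.

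Moran's I was computed over the 6 nearest level 7 spots on log-normalised values of spots with at least 100 UMIs, for genes with at least 100 UMIs in them, and 0.1 was taken as the threshold. On simulated stage 1 data with 200 genes that changed 4-fold across the section, it found 30 of them, 20 of the 20 with at least 1000 UMIs, and 7 of the flat genes among 7694, with a highest flat value of 0.115. Regions are Leiden groups (scanpy 1.11.5, leidenalg 0.10.2, resolution 0.5, 15 neighbours, 30 components, 2000 variable genes) of the same spots, and they were compared between sections only over genes not used to make them. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.

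The alternatives tried were TMM factors and DESeq2 size factors, minimum levels of 10 CPM and none, pseudocounts of 0.5 and 5 CPM, level 4 spots, spots with at least 100 UMIs, thinned counts, each stage 4 section alone and both summed. For outer and inner spots they were DESeq2, RLE factors, no low count filter, 50% and 25% of the spots on each side, level 4 spots, the 5 sections as blocks, no block, gaps not filled, spots with at least 100 UMIs, spots under 10 UMIs left out with the outline measured again, and each stage left out. For Moran's I they were 12 neighbours, thinned spots and level 4 spots, and for regions resolutions of 0.3 and 1.0, limits of 50 and 200 UMIs and another seed.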

Results

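Gene expression was mapped across floral buds of the water lily Nymphaea colorata, a member of an early-diverging lineage of flowering plants, at 4 stages that run from dividing floral meristems to nearly mature reproductive organs. Each bud was cut lengthwise into frozen sections of 10 µm, and the RNA of a section was caught on a slide whose spots carry position barcodes, so that each molecule counted (UMI) has a place in the tissue. Stages 1, 2 and 3 had 1 section each and stage 4 had 2 sections, which the labels do not assign to 1 bud or 2. The description of the series calls the 5 sections serial, although they span 4 stages. A difference among stages 1 to 3 therefore has no replicate check, and one to stage 4 is checked only by whether both of its sections pass. No p-value is given for differences between stages. The files list genes by ID alone and do not pair the IDs with gene names, so at most 2 IDs in each direction are named per comparison.

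The sections differed in size and in depth. At spot level 7, the stage 1 section held 3952760 UMIs in 1668 spots (median 1914 UMIs per spot), stage 2 held 5749377 in 2806 spots (median 1881) and stage 3 held 23421560 in 5354 spots (median 4309). Stage 4 section 1 held 1324101 UMIs in 11867 spots with a median of 26 UMIs, and stage 4 section 2 held 3053566 in 10175 spots with a median of 210. In stage 4 section 1, 33.5% of the spots had under 10 UMIs, against 0.482% in section 2 and 0 spots in stages 1 to 3. Of the 24059 genes listed, 17767 to 20077 had at least 1 UMI in a section.

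**Figure D1:**
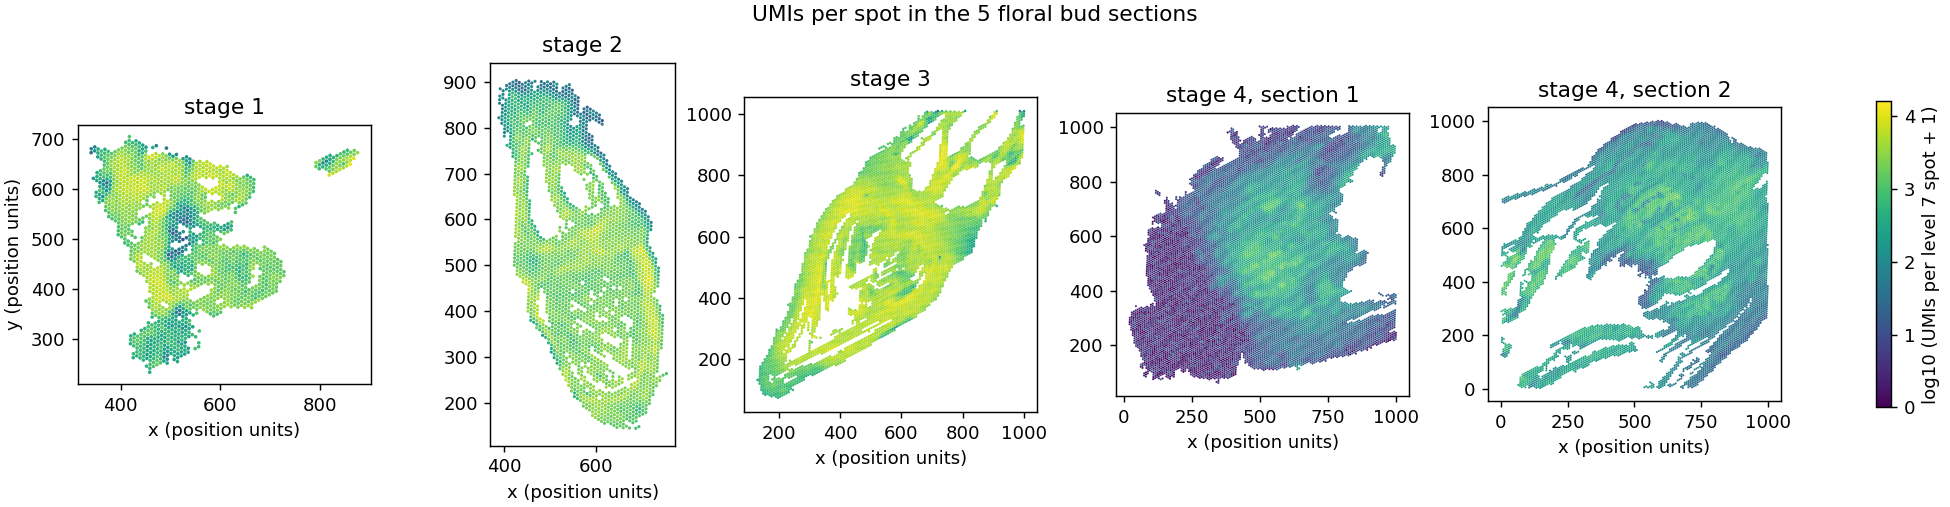
Spots of the 5 sections at their x and y positions (position units as deposited), each spot coloured by the log10 of its UMIs plus 1, at spot level 7. Stage 3 is the deepest section (median 4309 UMIs per spot), and the lower left of stage 4 section 1 is a wide area of spots with under 10 UMIs.

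From stage 1 to stage 2, 337 of 5355 genes with a level of at least 50 CPM in either stage (CPM is the count scaled to a common section total) were at least 2-fold higher and 401 were at least 2-fold lower. Nycol.B00172.v1.2 stood at 0.253 CPM (1 UMI) in stage 1 and 190 CPM (1095 UMIs) in stage 2, a ratio of 753 (95% exact interval of the counts 135 to 29762). Nycol.K00471.v1.2 stood at 2.02 CPM in stage 1 and 51.5 CPM in stage 2, a 25.4-fold difference (12.7 to 59.5); at spot level 4 it had a log2 difference of 4.07 but did not pass the rule. In the other direction, Nycol.J01667.v1.2 had 546 UMIs (138 CPM) in stage 1 and 0 in stage 2, which puts it at least 265-fold lower in stage 2, and it had 0 UMIs in every later section too. Nycol.C00656.v1.2 had 135 CPM in stage 1 and 0.174 CPM (1 UMI) in stage 2, a ratio of 778 (139 to 30793). Counting noise did not give such calls, since sections drawn at the real depths from 1 pooled profile had 0 genes past the rule in each direction. The balance of higher and lower genes depended on the scaling: 45.7% of the changed genes were higher in stage 2 by total UMIs, 30.6% with TMM factors (238 higher, 541 lower) and 26.2% with DESeq2 size factors (206 higher, 579 lower), which lower the stage 2 over stage 1 log2 ratio of all genes by 0.14 and 0.19.

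Stages 2 and 3 were the most alike pair among the 10 pairs of sections. Only 57 of 5259 genes were at least 2-fold higher in stage 3 and 47 were at least 2-fold lower, 1.98% of the genes compared. Nycol.A02655.v1.2 went from 4.52 to 77.0 CPM, a 17.03-fold difference (11.6 to 26.1), and Nycol.B00166.v1.2 from 19.0 to 115 CPM, a 6.06-fold difference (5.001 to 7.41). Nycol.B00172.v1.2, which was far above stage 1 in stage 2, was down at 1.54 CPM in stage 3, 124-fold below stage 2 (88.9 to 178). Nycol.O00446.v1.2 went from 62.4 CPM in stage 2 to 9.69 CPM in stage 3, a 6.44-fold difference (5.44 to 7.64).

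From stage 3 to stage 4, 409 of 6148 genes were at least 2-fold higher and 675 at least 2-fold lower in both stage 4 sections. Both comparisons share the stage 3 section, and independent lists would share 181 and 395 genes. The agreement does not set stage 4 apart from stage 3: with stage 4 section 1 as the shared section, stage 3 and section 2 were both higher in 1078 genes and both lower in 795. With section 2 as the shared section the counts were 662 and 852. The counts of this step are therefore not a measure of a stage effect. Nycol.I01592.v1.2 had 0 UMIs in stages 1, 2 and 3 and then 4424 UMIs (3341 CPM) in stage 4 section 1 and 14804 UMIs (4848 CPM) in section 2, at least 26085-fold and at least 37850-fold above stage 3. Nycol.H01342.v1.2 stood at 0.384 CPM in stage 3 and was higher in both stage 4 sections, but at very different levels, 184 CPM in section 1 and 12391 CPM in section 2. Nycol.A03412.v1.2 was at 196 CPM in stage 3 and at 2.27 CPM (3 UMIs) and 2.95 CPM (9 UMIs) in the stage 4 sections, ratios of 86.6 (29.6 to 420) and 66.6 (35.04 to 146). Nycol.B02296.v1.2 was at 113 CPM in stage 3, had 0 UMIs in stage 4 section 1, at least 49.96-fold lower, and 5.57 CPM in section 2, a 20.3-fold difference (12.7 to 34.95). The requirement that both stage 4 sections pass sets these counts: with section 2 alone 1337 genes were higher and 1348 lower, and with section 1 alone 1306 were higher and 1696 lower. Of the changed genes, 37.7% were higher in stage 4 by total UMIs and 23.7% with TMM factors (282 higher, 907 lower), which lower the stage 4 over stage 3 log2 ratio of all genes by 0.20.

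**Figure D2:**
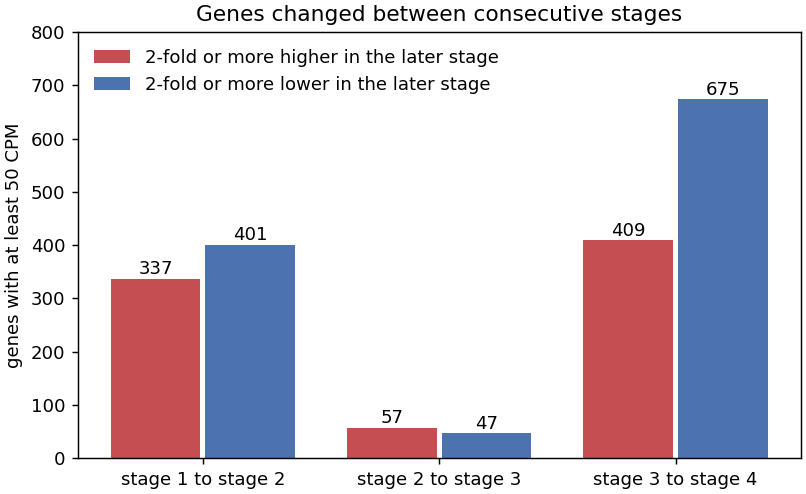
Number of genes with at least 50 CPM that were 2-fold or more higher (red) or lower (blue) in the later stage, for each step between consecutive stages; the stage 3 to stage 4 step needs both stage 4 sections on the same side. The stage 2 to stage 3 step has 57 and 47 genes, far fewer than the steps before and after it.

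Across the whole series, 6683 genes reached 50 CPM in at least 1 stage. Of these, 1389 were highest in stage 1, 1196 in stage 2, 1399 in stage 3 and 2699 in stage 4, where the stage 4 level is the mean of 2 sections that differ widely. With each stage 4 section required to agree, the numbers were 1145, 881, 1013 and 1368, and for 2276 genes the highest stage depended on the section. Genes at least 4-fold above every other stage numbered 51 in stage 1, 2 in stage 2, 0 in stage 3 and 95 in stage 4, and genes at least 4-fold below every other stage numbered 25, 0, 3 and 78; for stage 4 itself each section had to pass. With each section required throughout they were 42, 2, 0 and 95 above and 17, 0, 1 and 78 below. A level that climbed at every step, by 4-fold or more in all, was seen in 184 genes, and one that dropped at every step in 244. In any other order of the 4 stages, the reverse order aside, the count was at most 129. With both stage 4 sections required to pass, the counts were 87 and 147, and at most 73 in any other order.

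The pair of stage 4 sections differed from each other more than stage 2 differed from stage 3. Of 6502 genes with at least 50 CPM in either stage 4 section, 54.6% (exact 95% interval 53.4 to 55.8) were at least 2-fold apart, 1978 higher in section 2 and 1574 higher in section 1. Across those genes the log2 levels of the sections correlated at r = 0.19, and across all 24059 genes at r = 0.83; genes are not independent replicates. Nycol.H01342.v1.2 is an example, with 244 UMIs in section 1 and 37836 in section 2. The same share was 13.8% between stages 1 and 2 and 48.6% and 41.4% between stage 3 and each stage 4 section. Where a gene lay within the bud was in part shared by these sections: over 3657 genes with at least 50 CPM in outer or inner spots of each section, the log2 difference between outer and inner spots correlated at r = 0.66 between the stage 4 sections. It was 0.684 over 3378 genes with TMM factors, and 0.645 over 3783 genes with spots under 10 UMIs left out and the outline measured again.

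Spots near the outline of the tissue were then compared with spots deep inside it, with the 4 stages as blocks. For each stage the 33.3% of the spots nearest to the outline (outer) and the 33.3% farthest from it (inner) were summed. With edgeR's quasi-likelihood test, 59 of 15192 genes were higher in outer spots and 3 were higher in inner spots at a Benjamini-Hochberg adjusted p of 0.05, and 42 of the 59 and all 3 of the inner genes lay on the same side in 4 of 4 stages. The median log2 difference was 2.92 among the outer genes and −1.61 among the inner ones. Nycol.M00329.v1.2 was higher in outer spots by 4.38 on the log2 scale (SE 0.33, edgeR adjusted p = 0.00454), with mean levels over the stages of 46.3 CPM outer and 2.12 CPM inner. Nycol.G00710.v1.2 was higher in outer spots by 4.69 (SE 0.59, edgeR adjusted p = 0.0199), from 192 UMIs in all. Nycol.C01508.v1.2 differed by −1.93 (SE 0.31, edgeR adjusted p = 0.0450), with 11.2 CPM outer and 49.2 CPM inner, and Nycol.I01491.v1.2 by −1.61 (SE 0.24, edgeR adjusted p = 0.0350), with 23.7 and 63.9 CPM. Outer spots also held fewer UMIs than inner ones in every section, with medians of 1441 and 2441 in stage 1, 1526 and 2165 in stage 2, 3068 and 4523 in stage 3, 12 and 148 in stage 4 section 1, and 130 and 349 in section 2. The files do not tell whether the wide low-UMI area of stage 4 section 1 lies on tissue, and 1777 outer and 746 inner spots of that section had under 10 UMIs. With spots under 10 UMIs left out and the outline measured again, the medians there were 23 and 249, and edgeR called 56 outer and 2 inner genes, of which 55 and 2 were among those above.

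The test rests on 8 sums with 3 residual degrees of freedom, and in simulated data it recovered 0 of 50 genes changed 1.5-fold, 10 of 100 changed 2-fold and 41 of 50 changed 4-fold, so most 2-fold differences would be missed. Counts of called genes moved with the design: DESeq2 called 224 outer and 46 inner genes, without stage 2 or stage 3 edgeR called 9 and 11 outer genes and 0 inner ones, and with gaps inside the tissue counted as outline it called 29 and 8, of which 16 and 1 were among those above. Under that last setting none of the 4 named genes passed the test, and their log2 differences were smaller: 2.36 for Nycol.G00710.v1.2, 2.15 for Nycol.M00329.v1.2, −0.668 for Nycol.C01508.v1.2 and −0.486 for Nycol.I01491.v1.2. Without stage 2 or stage 3, Nycol.G00710.v1.2 was too low to be tested, and without stage 3 Nycol.M00329.v1.2 differed by 4.24 (edgeR adjusted p = 0.0558). The inner calls were not kept in any fit with 1 stage left out: none of the 3 was called. In these fits Nycol.C01508.v1.2 differed by −1.71 to −2.25 on the log2 scale (edgeR adjusted p 0.0647 to 0.251) and Nycol.I01491.v1.2 by −1.50 to −1.77 (0.0580 to 0.167), against −1.93 and −1.61 with all stages. The 10 inner genes called without stage 4 were others. Of the 59 outer genes, 35 were called without stage 1, 9 without stage 2, 7 without stage 3 and 30 without stage 4. Of all genes called above, outer and inner, 62, 60, 58 and 47 could be tested in these fits, in the same order. All of them kept their direction, but each fit shares its stages with the main one, so this is no independent check.

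**Figure D3:**
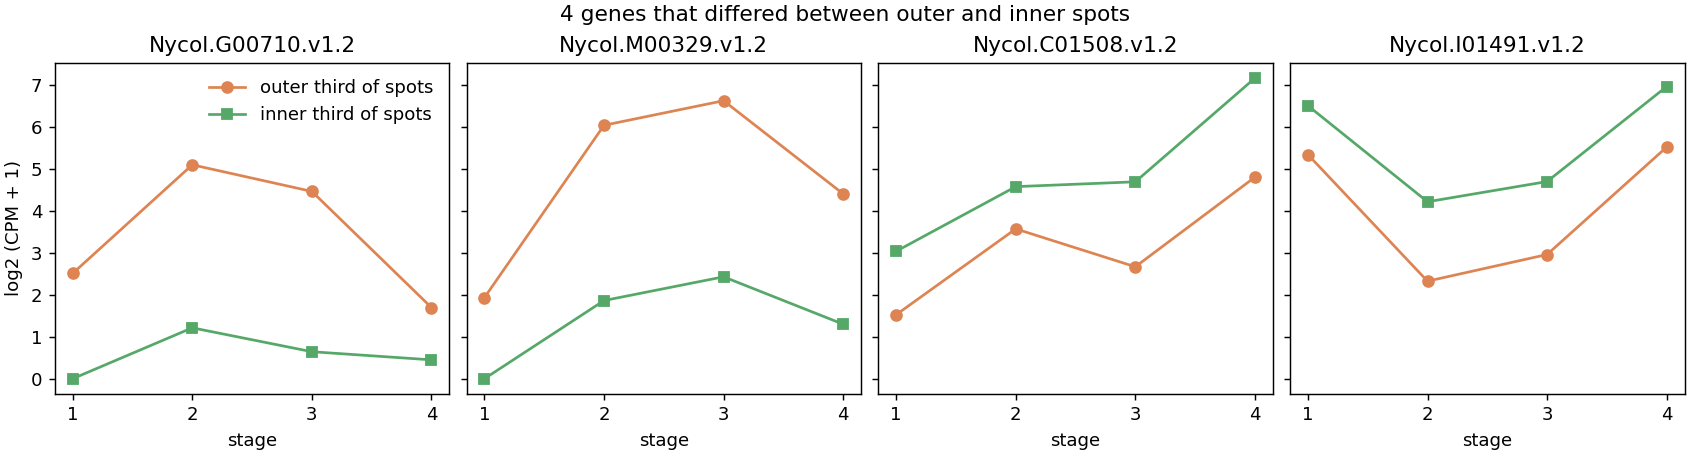
Level of 4 genes in outer (circles) and inner (squares) spots by stage, as log2 of CPM plus 1; each point is 1 sum of spots, with no error bar. Nycol.G00710.v1.2 and Nycol.M00329.v1.2 are higher in outer spots in 4 of 4 stages, and Nycol.C01508.v1.2 and Nycol.I01491.v1.2 are higher in inner spots in 4 of 4 stages. Some of these sides rest on few counts. Nycol.G00710.v1.2 had 4.69 CPM outer and 0 inner in stage 1, and 2.24 and 0.365 in stage 4. Nycol.M00329.v1.2 had 2.82 CPM outer and 0 inner in stage 1.

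The difference between outer and inner spots was most alike in stages 2 and 3. Over 7799 genes, the outer minus inner log2 difference correlated at r = 0.67 between stages 2 and 3, at 0.22 between stages 1 and 2, at 0.14 between stages 3 and 4, at 0.10 between stages 2 and 4, and at 0.02 and 0.01 between stage 1 and stages 3 and 4. Genes at least 2-fold higher in outer spots numbered 382 in stage 1, 372 in stage 2, 602 in stage 3 and 1059 in stage 4, and genes at least 2-fold higher in inner spots numbered 584, 206, 189 and 629. The balance depended on the scaling. These levels carry TMM factors; by total UMIs the counts were 788, 318, 423 and 748 for outer spots. For inner spots they were 305, 248, 333 and 1101. Stages 1 and 4 thus had the larger count on the other side by total UMIs. With spots under 10 UMIs left out, the stage 4 counts were 1107 outer and 679 inner with TMM factors, and 770 and 1198 by total UMIs. These counts are from 1 pair of sums per stage and carry no test.

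Many genes were patterned in space. Moran's I, which is 0 for a gene scattered over the section and near 1 for a gene whose neighbouring spots share its level, was at least 0.1 for 842 of 7694 genes with at least 100 UMIs in stage 1, 814 of 10077 in stage 2, 1604 of 13969 in stage 3, 43 of 2474 in stage 4 section 1 and 295 of 7159 in section 2. The depth of a spot also varies over a section. Of as many flat genes drawn at the real depth of each spot, 10 in stage 1, 2 in stage 2 and 0 in the other sections reached 0.1. Their highest values were 0.151, 0.105, 0.0801, 0.0416 and 0.0337 in the same order of sections. In stage 1, 508 genes lay above the highest flat value, and in stage 2, 773. Nycol.I01592.v1.2 had the highest value of both stage 4 sections, 0.918 and 0.829, and it was held by few spots: 50% of its UMIs lay in 104 of the 11867 spots of section 1 and in 182 of the 10175 spots of section 2. Nycol.C01489.v1.2 had the highest value of stage 3, 0.7495. Its values were 0.645 in stage 2, 0.306 in stage 1, and 0.0296 and 0.00934 in the stage 4 sections. Nycol.F00251.v1.2 had the highest value of stage 2, 0.717. Nycol.H01251.v1.2 led stage 1 with 0.610 and had 0.570 and 0.647 in stages 2 and 3. The index grows with depth: with each spot thinned to 100 UMIs the counts were 45, 41, 27, 29 and 96 in the same order, so the larger count of stage 3 is not a measure of more pattern. Thinned in this way, Nycol.H01251.v1.2 had 0.0907 in stage 1, Nycol.F00251.v1.2 0.291 in stage 2 and Nycol.C01489.v1.2 0.232 in stage 3. Nycol.I01592.v1.2 had 0.889 and 0.713 in the stage 4 sections. A lower index of a gene in a shallower section is therefore no evidence of a lost pattern.

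**Figure D4:**
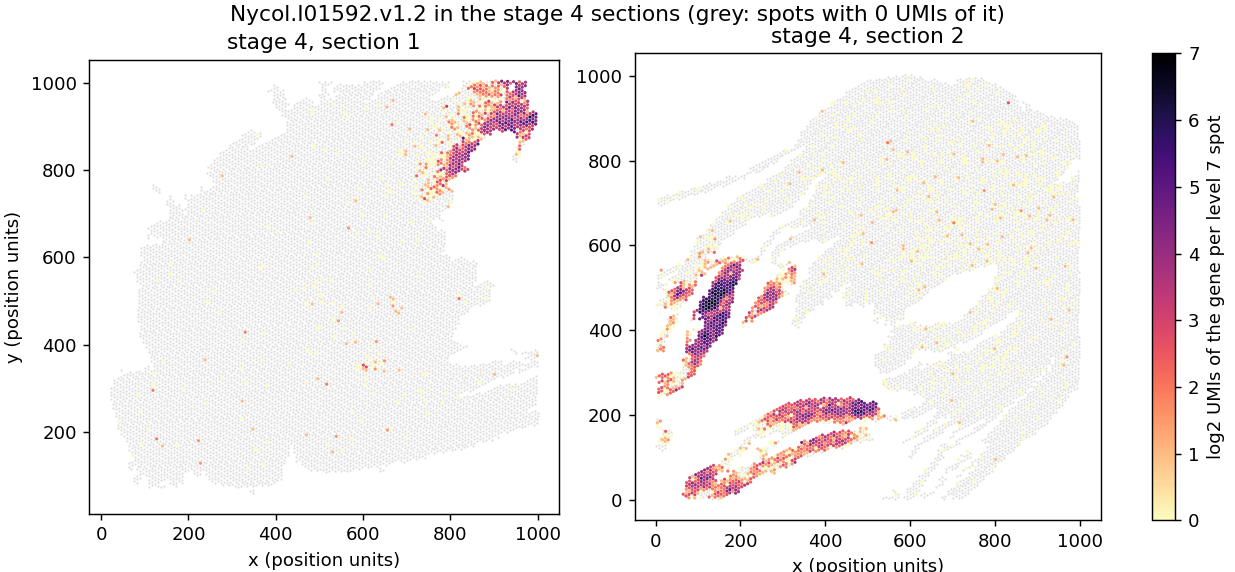
UMIs of Nycol.I01592.v1.2 per level 7 spot on a log2 colour scale at the x and y positions of the stage 4 sections, with spots without a UMI of the gene in grey. Its 4424 UMIs in section 1 lie mainly in 1 corner, and its 14804 UMIs in section 2 lie mainly in separate elongated pieces of tissue.

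Patterned genes were shared between sections. Stages 2 and 3 shared 737 genes with an index of at least 0.1 where 117 would be shared by independent lists, stages 1 and 2 shared 529 against 79.4, and the stage 4 sections shared 30 against 2.42. Of the 2025 genes measured in all 5 sections, 12 were patterned in each of them, against 0.00917 for independent lists, and 262 in stages 1 to 3. Genes of high depth pass the threshold more easily in every section, which adds to such sharing.

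Spots were also grouped by expression into regions, given here by number. The main grouping had 6 regions in stage 1, 7 in stage 2, 11 in stage 3 and 4 in each stage 4 section. In stages 1 to 3 the share of a spot's neighbours that lay in its own region was between 69.6% and 96.1% by region, and in stage 4 section 2 between 83.7% and 95.1%. In stage 4 section 1 it was 73.4%, 37.5%, 68.8% and 97.4% for regions 1 to 4, against 49.8%, 3.29%, 40.6% and 6.25% for scattered spots. Depth was itself patterned, with a Moran's I of log UMIs per spot of 0.763 to 0.841 over the sections. Regions also differed in depth: in stage 1 the median was 508 UMIs per spot in region 1 and 4229.5 in region 3. How far depth adds to these shares of neighbours was not tested. Over genes that were not used for the grouping, 5 regions of stage 2 and 5 of stage 3 were each other's best match, with a median r across genes of 0.67 and a highest r of 0.81. Between the stage 4 sections 3 pairs of regions were each other's best match, with a median r of 0.47, and between stage 1 and stage 3 there were 2 pairs, with a median of 0.57. The grouping moved with its settings in every section. The adjusted Rand index to the main grouping was 0.846 to 0.976 with another random seed, 0.508 to 0.758 with limits of 50 or 200 UMIs per spot, and 0.356 to 0.866 with resolutions of 0.3 or 1.0 in the sections other than stage 4 section 1. In that section it was 0.594 with another seed, 0.338 and 0.261 with the limits, and 0.171 and 0.216 with the resolutions. No region is named as an organ or cell type.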

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

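The tests of the tissue around single high spots, of genes of like count in section 2, of each gene counted once per spot, of UMI-matched spots and of TMM factors for genes on opposite sides were chosen after the results they bear on were seen.

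Some genes lay on opposite sides of the bud in different stages, at least 2-fold higher in outer spots of 1 stage and at least 2-fold higher in inner spots of the other, with at least 50 CPM in outer or inner spots of each section. There were 6 such genes between stages 1 and 2, 43 between stages 1 and 3, 28 between stages 1 and 4, 2 between stages 2 and 3, 11 between stages 2 and 4, and 10 between stages 3 and 4. The genes compared numbered 4444, 4363, 2703, 5008, 2881 and 2884 in the same order. For stage 4 each section had to be 2-fold on the same side, a stricter rule than for the other stages. How many such genes counting error alone would give was not computed. Genes 2-fold or more on the same side of both stages numbered 67, 49, 19, 150, 16 and 37 in the same order. These levels are scaled by total UMIs. With TMM factors the opposite genes numbered 6, 74, 23, 2, 8 and 10, and the direction turned where stage 1 was compared with stages 2 and 4. Genes outer in stage 1 and inner in stage 2 numbered 5 by total UMIs and 0 with TMM factors, and those on the reverse sides 1 and 6. Against stage 3 the numbers were 8 and 1, with 35 and 73 reversed, and against stage 4 19 and 9, with 9 and 14 reversed. So the side on which stage 1 differs from stages 2 and 4 depends on the scaling. These differences between stages were not tested, since stages 1 to 3 give 1 pair of sums each. Stage 1 is also a section of open shape with a detached fragment, in which distance to the outline reaches 90.2 units at most against 227 in stage 3.

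The stage 4 sections differed 2-fold or more in 54.6% of the genes. Counting noise at these depths gave 0%, which argues against it. With each gene counted at most once per level 4 spot, so that single spots carry no weight, 51.4% still differed, which argues against single-spot bursts as the whole cause. Between regions that were each other's best match in the sections, with at least 100000 UMIs on either side, the lowest share was 54.5%. This argues against different shares of these broad regions as the whole cause. The pairs matched only at r = 0.47 and 0.54, and the grouping of section 1 moved with its settings. Different shares of tissue within a region are therefore not excluded. The description of the series calls the sections serial, which does not settle whether these 2 come from 1 bud. Different buds, planes or parts of the bud, tissue lying in 1 section alone, and differences between the libraries stay open as untested candidate explanations.

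Stage 4 section 1 held genes with a large part of their UMIs in a single spot. Among genes with at least 50 CPM, 206 had over 25% of their UMIs in 1 level 4 spot, against 0 genes in each of the other sections, and 1 spot held 210 UMIs of Nycol.A02811.v1.2. Random splits of the spots of this section into equal parts differed 2-fold in 4.57% of the genes, against 0.0453% from counting alone and at most 0.0233% in the other sections. Tissue wider than 1 spot with a high level of these genes is argued against, since the 6 spots around the highest one held 1.70 times the UMIs expected from the rest of the section (17 UMIs, interval 0.991 to 2.72), and the 78 of these genes with at least 50 CPM in section 2 had a median largest-spot share there of 1.01 times that of all such genes. Another 125 genes with at least 10 UMIs in section 2 had a median ratio of 0.987 to genes of like count there. Its 95% bootstrap interval over genes, which treats them as independent, was 0.957 to 1.000. A ratio of 11.1 was expected if their UMIs were spread as in section 1. These values argue against a property of the genes for both sets, and the other 3 genes were too low to compare. Copies of single molecules counted as separate UMIs in a shallow library may be the source, but reads would be needed to test this, and a single cell with a very high level cannot be excluded.

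The 3978 spots of stage 4 section 1 with under 10 UMIs held 1.00% of its UMIs, and 503 of the spots in the section had 0. The summed profile of the 3978 spots correlated with that of the other spots at r = 0.52 across 4416 genes. Their sum holds only 13246 UMIs, so counting error alone lowers this r. The r that counting error would give was not computed, so the value does not show that the profiles differ.

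For the genes called between outer and inner spots, exchanging the positions within stages gives 8 splits with the real one included, too few for a share under 0.05. Only the real split, 1 of the 8, reached 62 calls, and the highest of the others called 5. In spots matched on UMIs between outer and inner, 89 outer and 6 inner genes were called, which include 51 of the 59 outer and 2 of the 3 inner genes called before. Nycol.C01508.v1.2 was not called (log2 −1.78, edgeR adjusted p = 0.0570). Of the 62 genes called before, 60 could be tested, with a median ratio of 0.960 of the log2 difference to its earlier value and 60 of 60 in the same direction. Inner spots with fewer UMIs were also compared with the other inner spots, a check added after the results were seen. Over 47 of the called genes this log2 difference correlated with the outer minus inner one at r = 0.475, and over 14224 genes at −0.00674. Among the outer genes of the 47 its median was 0.277, against 2.33 between outer and inner spots. In this check 0 genes passed the edgeR test.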

How the results depend on the processing

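The list alternatives applied to all genes for Moran's I, its flat genes drawn at real depths, the matched spots, stage 4 from section 2 alone, the capture window, the spots with at least 10 UMIs, the other scaling of outer and inner spots, the other shared sections, both stage 4 sections required for the series of stages and the count of each gene once per spot were chosen after seeing the data. Of 132 values of named genes between stages, 14 moved beyond counting error and 0 reversed, and of 68 values between outer and inner spots, 50 stayed past the edgeR or DESeq2 threshold and 18 did not; in 4 more fits of a gene it was too low to be tested (Nycol.G00710.v1.2 with no block and without stage 2 or 3, Nycol.M00329.v1.2 with no block). Between stages, the settings of 10 CPM and no minimum cannot change the value of a named gene. The named genes were also chosen as the furthest ones, so a reversal was unlikely from the start. Of 66 alternative counts of genes changed between stages, 48 were within 1.5 times the reported count, and no gene changed sides. Where a cause is not named it was not tested. A minimum of 10 CPM, which admits more genes, gave 919 higher and 800 lower from stage 1 to 2, 160 and 143 from 2 to 3, and 974 higher from 3 to 4. No minimum gave 1450 and 1414, 342 and 288, and 1388 and 1190. DESeq2 size factors gave 206 higher from stage 1 to 2. The stage 4 sections summed gave 982 and 1079, and each left out in turn 1306 to 1337 higher and 1348 to 1696 lower. The share of genes 2-fold apart between the stage 4 sections was 52.2% at 10 CPM, 39.6% with no minimum, 52.3% with a pseudocount of 5 CPM and 51.4% with each gene once per spot, and 54.6% to 55.2% otherwise.

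Outer and inner calls were 224 and 46 with DESeq2, 217 and 41 with no low count filter, 140 and 21 with 5 sections as blocks, 29 and 8 with gaps not filled (where the named differences were also far smaller), and 89 and 6 in matched spots. With no block edgeR called 0 and 0 (538 genes at an unadjusted p under 0.05). Leaving out each stage gave 9 to 62 outer and 0 to 10 inner genes, lowest without stage 2 (9) and stage 3 (11), and none of the 3 inner calls was kept in any of these fits. Nycol.K00471.v1.2 did not pass the rule at level 4. Without section 1 of stage 4 the counts were 62 and 3. Genes with a Moran's I of at least 0.1 numbered 45, 41, 27 and 96 in stages 1, 2 and 3 and stage 4 section 2 with spots thinned to 100 UMIs, and 297, 251, 546, 12 and 75 in the 5 sections at level 4, both of which leave fewer UMIs per spot. Of 25 alternative numbers of regions, 6 differed by over 1.5 times. The alternatives for gene lists and list genes could not be run, since the lists could not be filled. Between stages, no paired analysis was possible because stages 1 to 3 have 1 section each; outer and inner spots were compared within stages. Depth limits stage 4 section 1 most: 2474 genes there reached 100 UMIs in the spots used, against 13969 in stage 3.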

Other observations

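Genes whose IDs carry neighbouring numbers tended to share spatial patterns. Over 5572 genes with at least 1000 UMIs in stage 3, 3.13% of 1501 pairs with ID numbers 1 apart within the same letter had a correlation across spots of at least 0.2, against 1.204% of pairs 2 to 5 apart, 0.410% of pairs 6 to 20 apart and 0.281% of pairs 100 or more apart. If the numbers follow gene order, reads shared by directly adjacent gene models might explain the first of these. The median correlation of pairs 2 to 5 apart exceeded that of distant pairs by 0.00186, above the range of 0.00158 over 20 random draws of distant pairs. That excess cannot exclude shared reads, since 2 genes can each share reads with the gene between them. The draws also leave out the error of the nearer pairs. Duplicated genes with like sequence and regulation of neighbouring genes stay open, and neither could be tested without sequences. The shift is small, and most neighbouring pairs showed no shared pattern.

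Few genes changed at consecutive steps. From stage 1 over stage 2 to stage 3, 11 were higher at both the first and the second step, 8 were higher and then lower, 7 lower and then higher, and 4 lower at both. From stage 2 over stage 3 to stage 4, 4 genes were higher at both steps, 19 higher and then lower, 9 lower and then higher, and 0 lower at both. Consecutive steps share their middle section, which favours turns over runs, so the 19 is not evidence of a peak.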
